A study of Homo sapiens and Mus musculus with 20 samples.

How the data were processed

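Chromatin occupancy of the zinc finger transcription factor ZNF410 was measured by CUT&RUN, in which an antibody directs micrococcal nuclease to a protein in permeabilised cells and the released DNA fragments are sequenced. The 20 libraries fell into 8 groups by their labels. HUDEP-2 cells overexpressing HA-tagged ZNF410 gave 4 libraries with an HA antibody and 4 with IgG, unmodified HUDEP-2 cells gave 1 with a ZNF410 antibody and 1 with IgG, human CD34+ HSPCs gave 2 and 2, and mouse MEL cells gave 3 and 3. IgG was the negative control. The reads were paired-end, 42 bp long, per the labels' protocols.

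The values used were 4 peak lists, 1 for each cell setting, in which each peak had a position and a linear fold enrichment as deposited by the authors. The submitters' processing notes name Trimmomatic, Bowtie2, Picard, SAMtools and MACS2, with no version or setting, and the genome builds hg19 and mm10. The human lists were read as hg19 and the mouse list as mm10. The peak threshold, the use of an exclusion list for repetitive regions, and the way replicate libraries were pooled or combined are not given in the sources used here. The fold enrichment is therefore the authors' value for each peak of a list, without a standard deviation or a number of replicates. No antibody library could be compared with its IgG library. No per-library counts were used, so sequencing depth is unknown here and no counting interval or detection limit is given. Fold enrichment depends on antibody, depth and background, and it was used to rank and describe peaks within a list. Values from different lists are set side by side without a test.

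Positions are given as the lists give them. Whether their starts count from 0 or from 1 is not given in the sources used here, so a start or a width may be off by 1 bp. Widths were computed as end minus start plus 1. Overlaps between the 3 human lists were counted with bedtools 2.31.1, with a minimum overlap of 1 bp, and a reciprocal overlap of 50% and a distance of up to 1000 bp were the alternatives. Peaks were joined to the highest peak of their list across gaps of up to 10 kb, and the joined peaks are called the CHD4 cluster in human and the Chd4 cluster in mouse. This name comes from what is known of the study and of the position of the gene in both builds. No annotation or sequence of hg19 or mm10 was used, so other peaks are given by position. The supplied gene table describes GRCh38.p14, and only the order of genes was taken from it.

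Several analyses planned before the data were examined needed a genome sequence or annotation of these builds and were not run. These were the search for the ZNF410 motif, the comparison with random regions, the distance to transcription start sites, the genes shared between mouse and human, and the counts over lists of NuRD subunits, globin repressors, globins and erythroid factors. The rule for the named items was also fixed before the data were examined. It took every peak of a list of up to 10 peaks and the 25 peaks of highest fold in a longer list. Every peak at CHD4 or Chd4 was included. The rule further took peaks with the motif and peaks whose gene was in more than 1 list or in the gene lists above. Those parts could not be applied, so a peak near a gene of these lists may go unnamed here. In the longer lists the strongest of the peaks taken are given by position and the rest as a count with their range. Some peaks outside the rule were named or counted after their values were seen. They lay on chromosomes 3, 6, 9, 12 and 13, on the contigs and on the mitochondrial genome. The gap that defines a cluster and the window of 1 Mb around the highest peak were chosen after the data were seen. So were the limits of the stretches on chromosomes 3 and 13 and the grouping of peaks on multi-copy DNA. Multi-copy DNA here means the mitochondrial genome, unplaced contigs and the stretch of mouse chromosome 9 below 3.1 Mb, from general knowledge of these sequences, and copy number was not measured.

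The computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and matplotlib 3.10.9 for plots. The relation of fold and distance across peaks was tested by an exact two-sided permutation test, at a threshold of 0.05. Peaks of 1 list are not replicates, so this test describes the list and not the variation between samples. The code was tested on simulated data. All 40 planted overlaps among 150 simulated peaks were found, and 0 after the partners were moved away. For 9 peaks, a planted fall of fold with distance was called in 65 of 100 trials and a trend in its absence in 4 of 100. The planted fall had a single size, at distances drawn evenly up to 1 Mb. The 65 of 100 is therefore not the power for the measured peaks, which lay 24.0 to 621 kb away.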

Results

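The study asked where ZNF410 occupies chromatin in erythroid and haematopoietic cells. HUDEP-2 is an immortalised human erythroid progenitor line derived from umbilical cord blood, CD34+ HSPCs are primary human haematopoietic stem and progenitor cells, and MEL is a mouse erythroleukaemia line. The tagged protein was profiled with an HA antibody in overexpressing HUDEP-2 cells, and the endogenous protein with a ZNF410 antibody in the other settings. The overexpression list held 49 peaks, the HUDEP-2 list 5, the CD34+ HSPC list 5 and the MEL list 155, from 4, 1, 2 and 3 antibody libraries. All folds below are the authors' fold enrichments per peak, 1 value per peak, with no replicate error and at unknown depth.

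In HUDEP-2 cells overexpressing HA-tagged ZNF410, the highest enrichment lay at CHD4, which encodes the chromatin-remodelling ATPase of the NuRD repressor complex. The highest peak lay at hg19 chromosome 12, 6722170 to 6723355, with a fold enrichment of 77.1. The next lay at 6716540 to 6717821, with a fold of 56.6. The peak of lower coordinate covers the known start of CHD4, and the other lies upstream of the gene, 5.58 kb away from midpoint to midpoint. In the GRCh38.p14 gene table, the protein-coding neighbours of CHD4 are NOP2 on one side and LPAR5 on the other.

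These 2 peaks stood apart from the rest of the overexpression list in height and in width. The highest fold outside the CHD4 cluster was 9.78, and the leading peak was 7.88 times as high as that peak. The 2 CHD4 peaks were 1186 and 1282 bp wide, and no other peak of this list exceeded 500 bp. The median width of the 45 peaks outside the cluster was 95 bp. The cluster held 2 further, lower peaks, at 6714587 to 6714763 with a fold of 9.96 and at 6717969 to 6718309 with a fold of 7.07.

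The remaining 45 peaks of the overexpression list had a median fold of 4.47. A group of 3 of them lay on chromosome 12 within 1 Mb of the highest peak, at 6772340 to 6772589 (fold 4.50), 6798703 to 6798878 (fold 7.78) and 6833056 to 6833390 (fold 5.50). The other 42 were spread over the genome. They were not checked for repeated sequence, since the multi-copy group was applied to the MEL list only. The strongest were on chromosome 12 at 56831583 to 56831688, with a fold of 9.78, on chromosome 4 at 83934045 to 83934166, with a fold of 9.06, and on chromosome 17 at 77770820 to 77770914, with a fold of 7.94. Peaks on chromosome 6 at 28565907 to 28566034, on chromosome 11 at 59325022 to 59325132 and on chromosome 9 at 137299105 to 137299218 followed, with folds of 7.12, 6.74 and 6.42. Of the 25 peaks of highest fold, 4 belonged to the CHD4 cluster, 2 to the surrounding 1 Mb and 19 to other places. The 13 of these 19 not given by position had folds of 4.61 to 5.69, and the lowest of the 25 had a fold of 4.61.

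**Figure D1:**
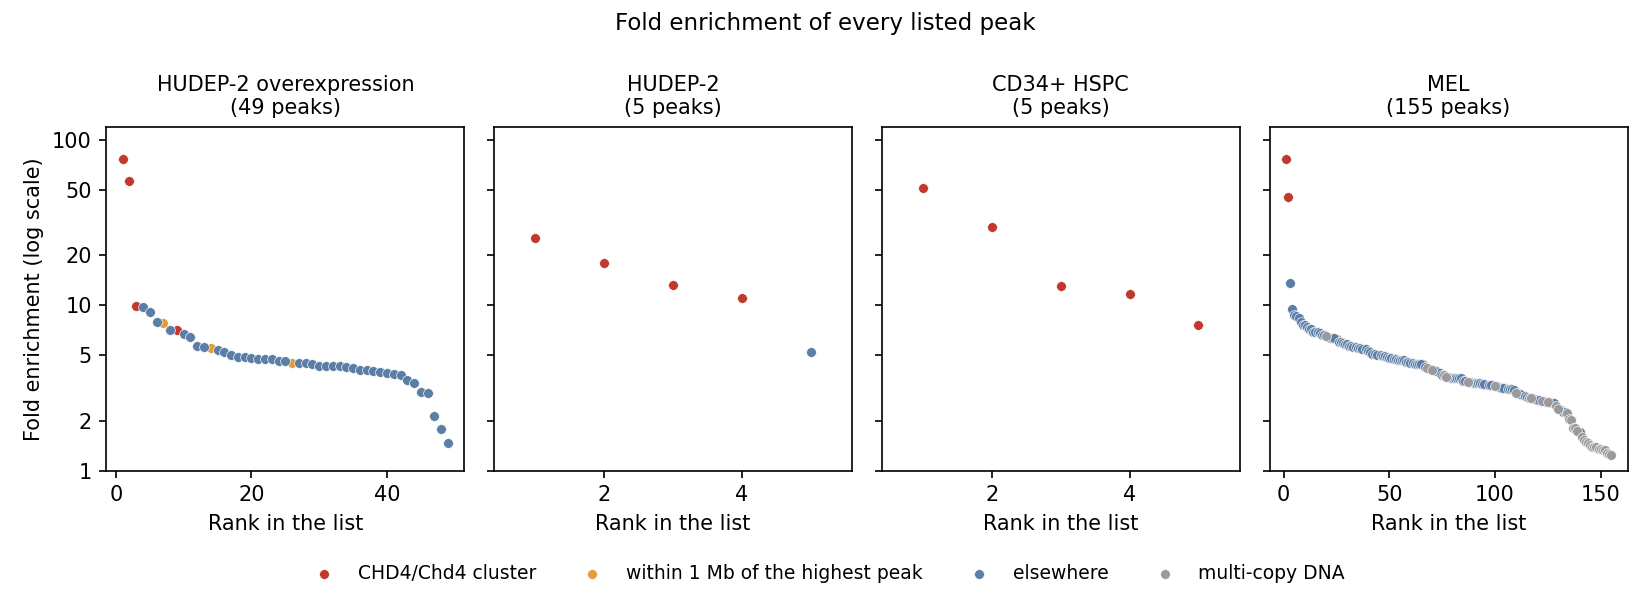
Fold enrichment (log axis) of every peak against its rank in each of the 4 lists, with 1 point per peak coloured by place: the CHD4/Chd4 cluster, the surrounding 1 Mb, multi-copy DNA (marked in the MEL list only) and elsewhere. In the 2 long lists, the leading pair of peaks at CHD4 or Chd4 lies above all others, with folds of 77.1 and 56.6 in overexpressing HUDEP-2 cells and 76.7 and 45.1 in MEL cells.

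The profile of endogenous ZNF410 in unmodified HUDEP-2 cells consisted almost entirely of the same locus. The 4 highest of its 5 peaks lay in the CHD4 cluster. At the start of the gene, a peak at 6716926 to 6717174 had a fold of 25.5 and a peak at 6717492 to 6717699 a fold of 11.1. In the upstream region, a peak at 6723006 to 6723280 had a fold of 17.9 and a peak at 6722177 to 6722366 a fold of 13.3. The only peak elsewhere was on chromosome 19 at 32925925 to 32926023, with a fold of 5.25, and the leading CHD4 peak was 4.87 times as high. This setting had 1 antibody and 1 IgG library, so it has no replicate check.

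In CD34+ HSPCs, all 5 peaks lay in the CHD4 cluster. A peak 1493 bp wide at 6716920 to 6718412 had a fold of 50.9, and a narrower one at 6716577 to 6716755 a fold of 11.8. In the upstream region, the peak at 6722580 to 6723376 had a fold of 29.7 and the peak at 6722192 to 6722377 a fold of 13.1. The fifth, at 6721200 to 6721451, lay between the 2 regions with a fold of 7.57.

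The human lists shared the CHD4 locus and no other position. With a minimum overlap of 1 bp, 4 of the 5 HUDEP-2 peaks and 4 of the 5 CD34+ HSPC peaks met a peak of the overexpression list, and 4 of the 5 HUDEP-2 peaks met a CD34+ HSPC peak. In the other direction, 2 of the 49 overexpression peaks met a HUDEP-2 peak and 3 met a CD34+ HSPC peak. None of the shared peaks lay outside the cluster, and the chromosome 19 peak of unmodified HUDEP-2 cells had no partner. The CD34+ HSPC list had 0 peaks outside the cluster and the HUDEP-2 list 1. Sharing at other positions was therefore hardly possible with these short lists. With a reciprocal overlap of 50%, the HUDEP-2 and overexpression lists shared 0 peaks, since the overexpression list has 1 broad peak where the HUDEP-2 list has 2 narrow ones.

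**Figure D2:**
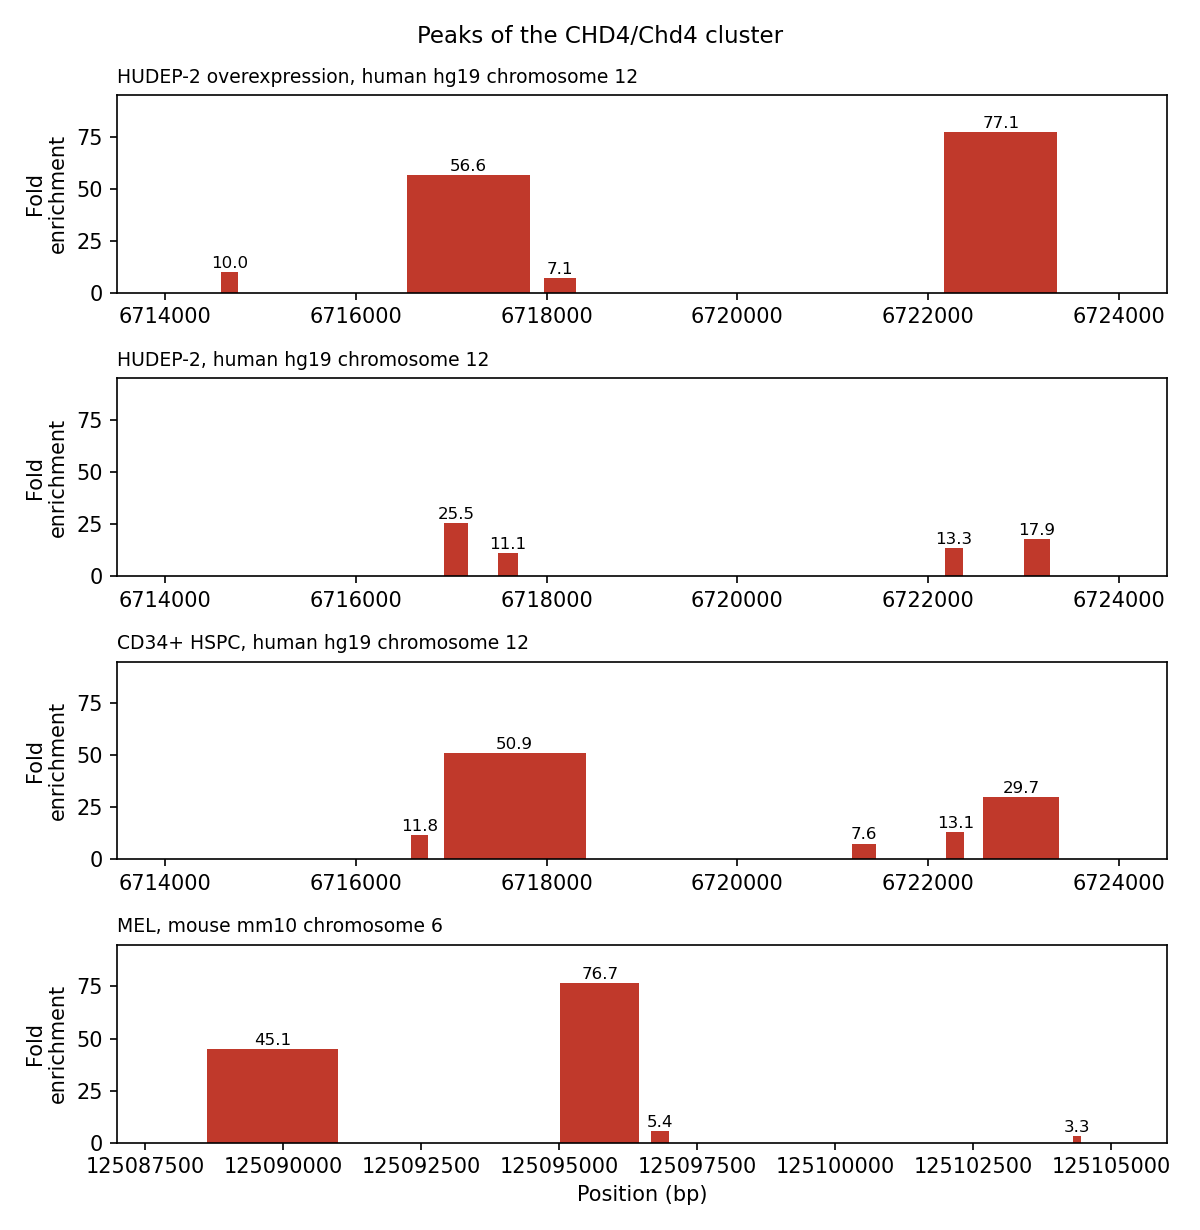
Peaks of the CHD4 cluster on hg19 chromosome 12 in the 3 human lists and of the Chd4 cluster on mm10 chromosome 6 in the MEL list, with each bar spanning a peak's start to its end (bp) and its height giving the fold enrichment on a linear axis from 0. Each list has its highest peaks in 2 regions, whose leading peaks lie 5.31 to 6.09 kb apart from midpoint to midpoint.

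In mouse MEL cells, the 2 highest of the 155 peaks lay at Chd4. The peak at mm10 chromosome 6, 125095024 to 125096451, which covers the known start of Chd4, had a fold of 76.7, and the peak at 125088617 to 125090996, upstream of the gene, had a fold of 45.1. Their midpoints were 5.93 kb apart, against 5.58 kb in overexpressing HUDEP-2 cells, 6.09 kb in unmodified HUDEP-2 cells and 5.31 kb in CD34+ HSPCs. In unmodified HUDEP-2 cells the upstream region held 2 peaks, and the one of lower fold lay 5.22 kb from the leading peak. These distances therefore depend on how each region was divided into peaks. The leading MEL peak was 5.65 times as high as the highest MEL peak outside the cluster. Lower peaks in the cluster lay at 125096660 to 125096980 with a fold of 5.42 and at 125104312 to 125104457 with a fold of 3.27.

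The order of the 2 regions differed between the lists. The region at the start of the gene was the higher in unmodified HUDEP-2 cells, by a factor of 1.42, in CD34+ HSPCs, by 1.71, and in MEL cells, by 1.70. In HUDEP-2 cells overexpressing the tagged protein, the upstream region was the higher, by 1.36. With 1 value per peak and different antibodies, this difference in order was not tested.

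Outside the cluster, the MEL list held 151 peaks with a median fold of 3.64. Chromosome 13 carried 14 of them between 21.7 and 23.8 Mb, a stretch known to hold the major cluster of mouse histone genes, with a median fold of 6.89. The highest of these, at 21716146 to 21716391, had a fold of 13.6, the third highest of the list. Further peaks of this stretch lay at 23543308 to 23543654 with a fold of 9.44, at 23750965 to 23751122 with a fold of 8.67 and at 23745453 to 23745663 with a fold of 7.93. It supplied 10 of the 25 peaks of highest fold. On chromosome 3, 7 peaks between 95624723 and 96269681 had folds of 2.68 to 4.13. Of these, 4 lay between 96219692 and 96269681, near another known group of histone genes, with folds of 3.66 to 4.13, and the other 3 had folds of 2.68 to 3.38. Which genes or repeats these peaks meet was not examined and no enrichment for histone genes was tested, because no mm10 annotation was used.

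Other MEL peaks of high fold lay on other chromosomes. The strongest were on chromosome 2 at 119618600 to 119618836 with a fold of 8.77, on chromosome 7 at 3665487 to 3665828 with a fold of 8.33, on chromosome 10 at 128549104 to 128549322 with a fold of 7.63, on chromosome 11 at 58954446 to 58954593 with a fold of 7.57 and on chromosome 11 at 23069091 to 23069249 with a fold of 7.39. Another 12 of the 25 peaks of highest fold, 6 of them on chromosome 13, had folds of 6.30 to 7.23, and the lowest of the 25 had a fold of 6.28.

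On chromosome 6, 9 further MEL peaks lay within 1 Mb of the highest peak, from 124474655 to 125215498, with folds of 2.58 to 6.28. The strongest was at 125071659 to 125071828.

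A separate group of 35 MEL peaks lay on multi-copy DNA. The mitochondrial genome had 15, with folds of 1.25 to 2.04, and they covered 7939 bp. The stretch of chromosome 9 from 3002134 to 3031918 had 11, with folds of 1.75 to 4.17. The unplaced contig JH584304 had 8, with folds of 1.35 to 6.52. The contig GL456389 had 1, with a fold of 1.48.

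**Figure D3:**
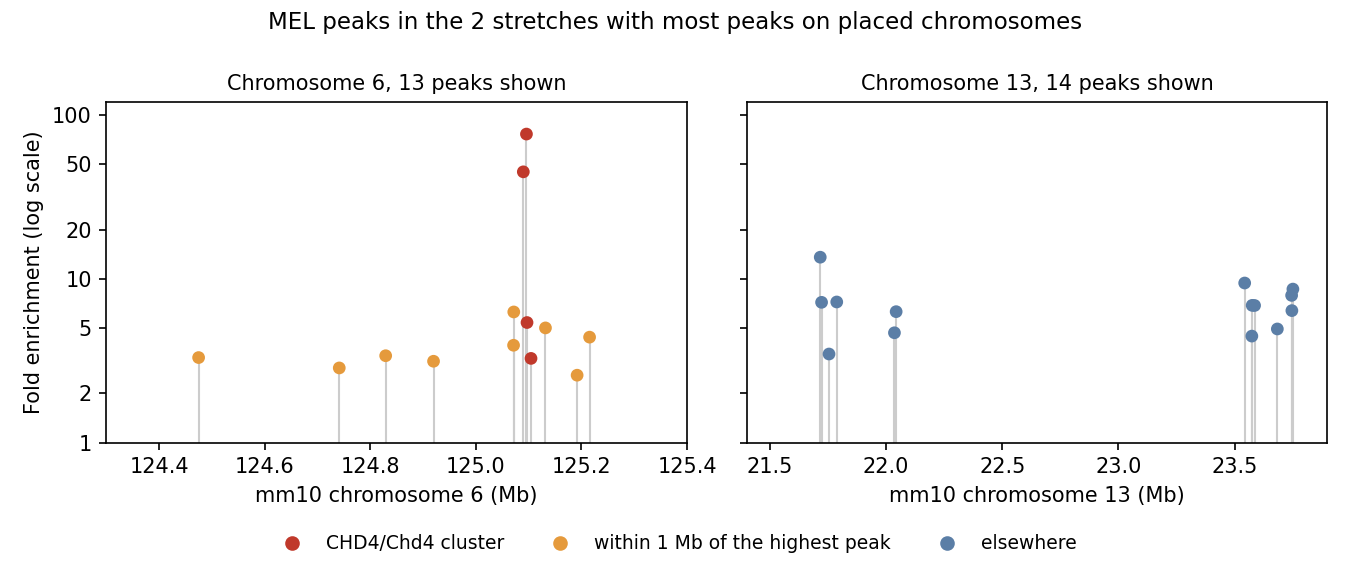
Fold enrichment (log axis) of MEL peaks against mm10 position (Mb) around the Chd4 cluster on chromosome 6, with 13 peaks, and in the chromosome 13 stretch, with 14 peaks; each point is 1 peak. The pair at Chd4 reaches 76.7 and 45.1, and the chromosome 13 peaks have folds of 3.48 to 13.6.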

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

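Nothing here could be recomputed without a replicate, since each list has 1 value per peak and no value per library. No paired analysis was possible because the lists hold no values for single libraries. The alternatives by q or p value, by motif mismatches and motif window, by distance to start sites and by shared gene were not run, since the lists give neither q nor p and no sequence or annotation of hg19 or mm10 was used. A value was counted as moved when it changed by more than 1.5 times. The cluster gaps, the ranking by width and the alternatives for the multi-copy and distance results were chosen after seeing the data. The CHD4 and Chd4 peak pair held ranks 1 and 2 in each list by fold and by width. Rank 1 by fold was fixed, since each cluster was built around the highest peak of its list. The second peak of each pair was the highest cluster peak more than 3000 bp from the first, a rule that was not planned. Rank 2 by fold and the ranks by width were not fixed by construction. However, 4 of the 5 HUDEP-2 peaks and all 5 CD34+ HSPC peaks lay in the cluster. Those short lists therefore left little room for another outcome. Keeping only peaks at or above the median fold left 25 of 49 overexpression, 3 of 5 HUDEP-2, 3 of 5 CD34+ HSPC and 78 of 155 MEL peaks by construction, and 5 of the 35 multi-copy peaks. Merging peaks within 1000 bp left 3 HUDEP-2 and 2 CD34+ HSPC peaks. A reciprocal overlap of 50% lowered the shared HUDEP-2 peaks from 4 to 0 against the overexpression list and from 4 to 1 against CD34+ HSPCs, and the shared CD34+ HSPC peaks from 4 to 2 against the overexpression list. Gaps of up to 100 kb enlarged the cluster from 4 to 7 peaks in overexpressing HUDEP-2 cells and from 4 to 9 in MEL cells. Unknown depth limits the short lists: a site missing from them is not shown to be unoccupied.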

Other observations

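The test in this part was chosen after the data were seen.

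Further peaks lay around the Chd4 cluster in MEL cells. Of the 11 chromosome 6 peaks outside the cluster, 9 lay within 1 Mb of the highest peak. Their median fold of 3.40 was close to the 3.66 of the whole list, which includes the multi-copy peaks. It was below the 4.48 of the 107 peaks outside the cluster, its surroundings and multi-copy DNA, a difference not tested. Grouping was not particular to Chd4, since 14 of the 15 chromosome 13 peaks lay in 2.03 Mb whose highest fold was 13.6. A signal that spreads from the Chd4 sites to nearby chromatin may contribute and predicts a fold that falls with distance, and over the 9 peaks, 24.0 to 621 kb away, Spearman's rho was -0.60 (exact permutation test, two-sided, p = 0.0968; rho -0.60 and p = 0.242 over the 6 peaks within 250 kb). The nearest pair of the 9, at 125071182 to 125071471 and 125071659 to 125071828, lay within 1000 bp of each other. The test counted them as separate peaks, though they may not be separate sites. A spreading signal stays open, as do further binding sites in the same stretch and a regional difference in accessibility, neither of which was tested.

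In overexpressing HUDEP-2 cells, the 3 peaks of chromosome 12 that lie within 1 Mb of the highest peak but outside the CHD4 cluster were 176, 250 and 335 bp wide, against a median of 94.5 bp over the 42 peaks elsewhere. Of those 42, 3 were at least 176 bp wide, from 183 to 251 bp.

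The 35 MEL peaks on multi-copy DNA had a mean log2 fold of 1.05 ± 0.627 (SD over 35 peaks), and the 120 other peaks 2.18 ± 0.714 (SD over 120 peaks). The 20 multi-copy peaks outside the mitochondrial genome had 1.435 ± 0.554 (SD over 20 peaks). The highest, on JH584304 at 87806 to 88157, had a fold of 6.52. These values do not tell background from occupancy, since the lists hold no IgG values.

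In the overexpression list, 28 of the 49 peaks were at most 100 bp wide and the narrowest was 84 bp, with reads of 42 bp, while the narrowest MEL peak was 116 bp wide. Some peaks at different positions shared their fold to every deposited decimal, 5 in the overexpression list and 18 in the MEL list, and the highest such fold was 4.70 and 5.55.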
